A study of Homo sapiens with 9 samples.

How the data were processed

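Bulk poly(A) RNA sequencing was performed on THP-1 cells, a human monocytic leukaemia line, that had been differentiated for 5 days with IL-4 and GM-CSF, exposed to a test compound for 24 h, and then matured with IL-4, GM-CSF, TNF-α and ionomycin for 72 h, so that exposure lasted 96 h in all. The 9 libraries formed 3 groups of 3, namely 0.1% DMSO vehicle control, perfluorooctanoic acid (PFOA) and perfluorooctane sulfonic acid (PFOS), and group and replicate number came from the sample titles. A DMSO percentage was available for the control libraries only, not for those with PFOA or PFOS.

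The deposited table holds a non-negative signal per Ensembl gene and library, read counts divided by a library size factor, for 60605 genes. The authors' scaling tool, strand setting and annotation release are not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 1.16, HISAT2 2.2.1, SAMtools 1.9, HTSeq 0.11.2, limma 3.50.3 and edgeR 3.36.0 with the build GRCh38.p13, with no role or order stated. Dividing each library by its smallest step gave whole reads for 100% of values within a tolerance of 1e-06, and those steps equalled the inverse of median-of-ratios size factors over the 9 libraries. The recovered totals ran from 67727355 to 106443316 reads per library. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom of any pair being 31.2.

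Gene symbols were taken from a table of Ensembl identifiers, which matched 60463 of the 60605 identifiers, with GENCODE release 29 names where a symbol was missing there. Coordinates are those of GENCODE release 29 on GRCh38, 1-based. Because strand use is unknown, reads of overlapping or antisense genes cannot be told apart.

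Genes with a value of at least 10 in at least 3 of the 9 libraries were tested, 19593 in all. Values were transformed to log2(value + 1), so that a fold change is on that scale and understates the change of low genes. A linear model over all 9 libraries, with 1 shared estimate of the spread, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Intervals are 95% intervals from this model.

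The design, most of the alternatives, 30 gene lists and the rule for naming genes were fixed before the data were examined. By that rule, the text draws on the 8 largest rises and 8 largest falls per comparison among called genes with a symbol, a mean of at least 100 in the higher group and no overlap between groups, on up to 4 called members of each list (or up to 2 of its most abundant members, given as values), and on a fixed panel of 16 maturation, lineage and lipid genes. Some genes picked by the rule are not reported here. The lists covered dendritic cell maturation, lineage, presentation, myeloid and other cell type markers, cytokines, NF-kB, interferon, calcium, PPAR, sterol, fatty acid, LXR, NRF2, heat shock, stress, aryl hydrocarbon receptor, p53, cell cycle, glycolysis, respiration, lysosome, uptake, matrix, histone and ribosomal genes. The 28 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists and the 3 comparisons together, and again with an estimated correlation. fry, which tests a list by itself against no change, was run as an alternative. For each list, calls were also counted with p adjusted over the list alone.

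The same procedure was tested on simulated data drawn from the real genes' means and library sizes, with 50 genes changed by each of 4 fold sizes. Changed genes had a mean of at least 50, so lower genes are not covered. In the simulation of PFOA against control over 19246 genes, it called 36% of genes changed 2-fold, 92% of those changed 4-fold and 100% of those changed 8-fold. The 16 false calls were 8.89% of all its calls. In that of PFOS against control over 19244 genes, the shares were 46%, 90% and 98%. The 12 false calls were 6.70% of all its calls. Both false shares lay above the 0.05 aimed at. Genes were drawn independently there, with 1 spread for all groups, so the simulation does not carry the differences between libraries of a group that the real data hold.

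Both compounds were compared with the same 3 controls. Unchanged groups were therefore simulated 100 times from the residuals of the real libraries, pooled over the 3 groups, keeping the correlation between genes. Alternatives were other scalings (TMM and quantile), pseudocounts of 0.5 and 5, no filter or a mean of at least 50, each library left out, the replicate number as a block, the 2 groups alone, robust variances, sample quality weights, a 2-fold minimum, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 Wald tests on the recovered reads. A limma-voom fit and a fit without PFOA replicate 1 and PFOS replicate 1 were added after seeing the data.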

Results

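Gene expression was measured in mature dendritic cells derived from THP-1 cells after 96 h with PFOA, PFOS or vehicle. Both compounds are perfluorinated surfactants that persist in the environment, PFOA ending in a carboxylate and PFOS in a sulfonate. Both were given at 10 µg/mL, which the labels state as 24.4 µM for PFOA and 20 µM for PFOS, so the mass doses matched and the molar doses differed. Each group held 3 libraries. Replicates 1, 2 and 3 had 67727355, 72056473 and 78876925 reads in the control group, 68528491, 82154690 and 106443316 with PFOA and 76241530, 81374044 and 74930790 with PFOS. Values below are normalised read counts as mean ± SD, n = 3. The labels name the replicates as separate samples without saying that they were separate cultures, so p-values measure the spread between these samples, which may be technical.

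The spread between libraries differed by group. The median SD of log2 values over genes was 0.17 in controls, 0.28 with PFOA and 0.37 with PFOS. PFOA replicates 2 and 3 correlated at r = 0.992 across genes, while PFOA replicate 1 correlated with them at 0.973 and 0.971 and with PFOS replicate 2 at 0.984. On the first principal component, which held 58.6% of the variance, controls lay between -65.9 and -44.6 and PFOA libraries between 27.8 and 94.0. PFOS replicate 1 lay at -66.3, beside the controls, while PFOS replicates 2 and 3 lay at 73.2 and 7.03.

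**Figure D1:**
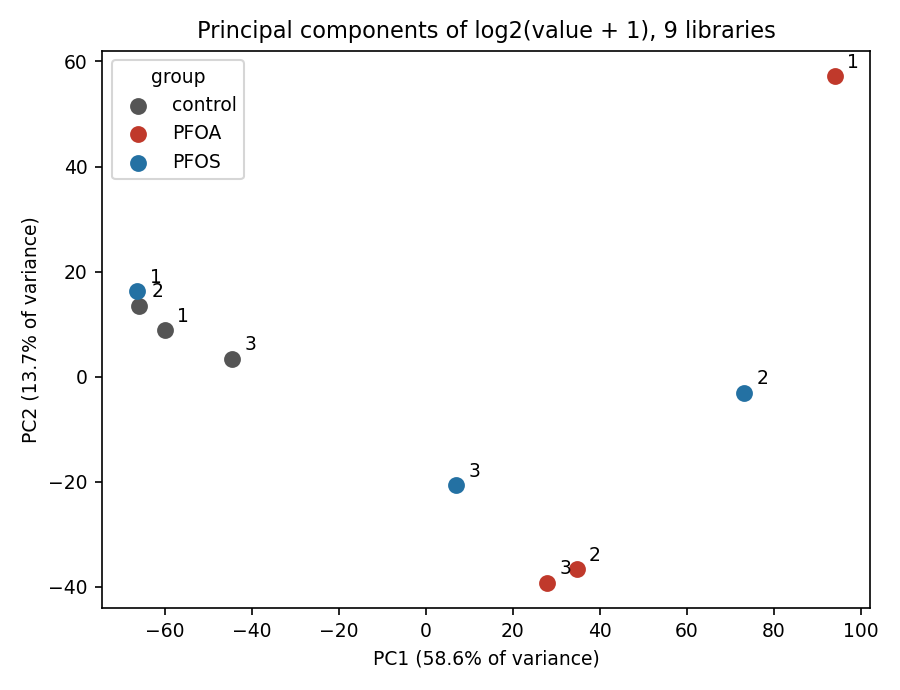
First and second principal components of log2(value + 1) over 19593 genes, with 1 point per library, coloured by group and numbered by replicate. PFOS replicate 1 lies with the 3 controls at -66.3 on the first component, and PFOA replicate 1 lies farthest from them at 94.0.

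The comparison of PFOA with vehicle asks which genes of these maturing cells respond to PFOA. PDK4, C1QA and C1QB rose with the smallest adjusted p of all genes. PDK4, a kinase that restrains pyruvate oxidation (ENSG00000004799, chromosome 7, 95583499 to 95596491), rose from 83.2 ± 15.8 to 3141 ± 1142 (log2 fold change 5.17, limma adjusted p = 0.000304). C1QB, a chain of complement C1q (ENSG00000173369, chromosome 1, 22652762 to 22661538), rose from 16.6 ± 5.27 to 421 ± 156 (log2 fold change 4.57, limma adjusted p = 0.00122). CD274, which encodes the checkpoint ligand PD-L1, fell from 1775 ± 153 to 476 ± 297 (log2 fold change -2.06, adjusted p = 0.0337).

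In total, limma called 1143 of 19593 genes with PFOA, 464 higher and 679 lower, of which 767 changed at least 2-fold. PFOA and control libraries were fully separated in each of the 1143 and in 9132 of all genes tested (46.6%), where chance gives 10%. The largest rises besides PDK4 and C1QB were ADORA3 (log2 fold change 5.91), ANGPTL4 (5.13), the potassium channel gene KCNJ2 (4.08), TMIGD3 (4.03), the formyl peptide receptor gene FPR2 (4.00) and SIGLEC16 (3.83). Among the largest falls were SLED1 (-5.53), DNAJC19P5 (-4.48), the nuclease gene DNASE1L3 (-3.89), SMTNL2 (-3.73), a Y RNA (-3.38), the tight junction gene CLDN1 (-3.30) and the serine dehydratase gene SDS (-2.85). ADORA3 overlaps TMIGD3, SLED1 lies within ACSL1 and DNAJC19P5, a pseudogene, within NFE2L2, each on the same strand, and SIGLEC16, Y RNAs, MT1E and HSPD1 have near-identical copies, so their counts are uncertain. Of the 68 called genes that the naming rule picked, PDK4, C1QA and C1QB stayed called whichever library was left out, and 3 to 13 genes in all stayed called without a given control or PFOA library. The number of calls was 13, 3 and 11 without control replicate 1, 2 or 3, 50, 3 and 6 without PFOA replicate 1, 2 or 3, and 5051, 4165 and 16 without PFOS replicate 1, 2 or 3. It was 433 with no filter, 5352 with PFOS left out of the fit, 8688 with sample weights, 4283 by DESeq2 and 4619 without PFOA replicate 1 and PFOS replicate 1 together, a fit chosen after seeing the data.

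Of 21 tested PPAR targets and fatty acid oxidation genes, 8 rose and none fell with PFOA (16 higher, adjusted over the list alone). Besides PDK4, they included ANGPTL4, a secreted inhibitor of lipoprotein lipase (22.4 ± 16.7 to 1076 ± 1169, adjusted p = 0.0352), PLIN2, a lipid droplet coat protein (18836 ± 6793 to 85542 ± 14818, adjusted p = 0.0204), and CPT1A, which admits fatty acids to mitochondria (2420.0 ± 162 to 5435 ± 479, adjusted p = 0.013). ACSL1 rose with a log2 fold change of 1.01. Among 14 fatty acid synthesis genes, FADS1 (0.72) and ACACA (0.75) rose (5 higher and 1 lower, adjusted over the list alone). Of 24 cholesterol synthesis genes PMVK rose (0.75; 1 higher, adjusted over the list alone), whereas HMGCS1 (0.22, adjusted p = 0.306) did not pass. Of 10 LXR targets PLTP rose (0.65; 2 higher and 1 lower, adjusted over the list alone).

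Monocyte and macrophage markers rose in 7 and fell in 1 of 23 tested members with PFOA (12 higher and 2 lower, adjusted over the list alone). C1QA rose from 311 ± 40.2 to 1493 ± 248 (adjusted p = 0.00122), C1QC with a log2 fold change of 2.36, VCAN of 2.36 and CD14 of 1.42. The list's median against the control mean was 1.57, 1.43 and 1.19 in the PFOA libraries, 1.28 and 1.08 in PFOS replicates 2 and 3, and -0.44 in PFOS replicate 1. Of 20 dendritic cell lineage markers FLT3, CD1D and MRC1 rose (2.08, 1.38 and 1.54; 4 higher and 1 lower, adjusted over the list alone). Of 15 uptake and scavenger receptors 4 rose, among them TLR2 (1.23), SCARB2 (1.01) and FCGR2A (0.67; 6 higher, adjusted over the list alone). Of 9 progenitor markers SRGN rose (0.83; 1 higher, adjusted over the list alone).

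Classical maturation markers did not pass the test. CD80 was 274 ± 94.6 in controls and 337 ± 190.3 with PFOA, CD83 1728 ± 598 and 3366 ± 3026, CD86 2859 ± 1139.8 and 6328 ± 2399, CD40 2688 ± 248 and 4027 ± 1075, and CCR7 122 ± 30.2 and 105 ± 39.7. Of 22 alternatives 2 called CD86 and 1 called CD40, and none called CD80, CD83 or CCR7. For CD86 limma gave adjusted p = 0.147, and 0.0332 without PFOS replicate 1. These data thus do not show that PFOA left the markers unchanged. Of 23 tested maturation genes only CD274 and CD70 (-0.75) were called, both lower (2 lower, adjusted over the list alone). Of 14 MHC class II genes IFI30 fell (-1.92; 2 lower, adjusted over the list alone), while HLA-DRA (-0.43, adjusted p = 0.325) and CIITA (0.63, adjusted p = 0.0954) did not pass. None of 18 MHC class I genes was called (0, adjusted over the list alone), nor were the panel genes CD209 (0.17) and CD1A (0.42).

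Of 31 interferon-stimulated genes 5 rose and 1 fell with PFOA (21 higher and 1 lower, adjusted over the list alone), with OASL (2.02), OAS2 (1.82) and HERC5 (0.76) higher and IRF9 (-0.87) lower. Among 25 cytokines and chemokines, CCL20 rose (3.24) and CXCL8, the neutrophil attractant, fell (-1.57; 2 higher and 5 lower, adjusted over the list alone). The median of this list was 1.06 in PFOA replicate 1, against -0.64 and -0.55 in replicates 2 and 3. Of 21 NF-kB targets SOD2 (-0.78) and TNFAIP2 (-1.34) fell (4 lower, adjusted over the list alone). Of 13 calcium-responsive genes FOS, EGR1 and RCAN1 rose (3.45, 2.96 and 2.03; 3 higher, adjusted over the list alone). The calcium list had a median of 2.11 in PFOA replicate 1, against -0.31 and -0.53 in replicates 2 and 3. In PFOA replicate 1, replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median of 1.15, against -0.11 and -0.30 in replicates 2 and 3, and mitochondrially encoded mRNAs 1.04, against -0.58 and -0.86.

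Several antioxidant, hypoxia and stress genes fell with PFOA. Of 23 NRF2 targets 5 fell, among them HMOX1, which degrades heme (32682 ± 7552 to 12995 ± 3226, adjusted p = 0.0337), OSGIN1 (-2.10), SLC7A11 (-1.28) and GCLM (-1.17; 3 higher and 8 lower, adjusted over the list alone). Of 25 glycolysis and hypoxia genes 4 fell, namely VEGFA (-1.35), PFKFB3 (-1.64), PDK1 (-1.03) and HK2 (-1.76), and 1 rose (7 higher and 5 lower, adjusted over the list alone). SESN2 fell among 23 unfolded protein and integrated stress genes (-1.45; 9 lower, adjusted over the list alone). The apoptosis genes BBC3 (-2.61) and TNFRSF10B (-0.68) fell among 18 p53 targets (1 higher and 6 lower, adjusted over the list alone). Of 28 lysosome genes ATP6V1A (-0.78), ATP6V1H (-1.02) and NPC1 (-1.64) fell (6 lower, adjusted over the list alone). NFE2L2 (-1.13) and AHRR (-0.66) fell among 4 tested aryl hydrocarbon receptor targets (1 higher and 3 lower, adjusted over the list alone). MT1E (0.92) and HSPD1 (0.60) rose among 15 metallothionein and heat shock genes (5 higher and 1 lower, adjusted over the list alone), and PLAU fell among 22 matrix genes (-2.05; 4 higher and 1 lower, adjusted over the list alone).

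No member was called, over all genes or adjusted over the list alone, among 27 cell cycle, 32 nuclear respiratory, 13 mitochondrially encoded, 31 ribosomal protein and 10 histone genes or 3 epithelial, fibroblast and erythroid markers. Cell cycle genes had a median log2 difference of 1.24 and 1.35 in PFOA replicates 2 and 3 and 0.11 in replicate 1. Of 13 lymphocyte markers GNLY rose (1.25; 1 higher, adjusted over the list alone). Against all other genes, camera placed PPAR targets (adjusted p = 8.96e-09), interferon-stimulated genes (4.04e-06), monocyte and macrophage markers (1.06e-05), cell cycle genes (4.94e-05) and uptake receptors (0.00371) higher with PFOA, and stress (0.00371) and NRF2 (0.0128) genes lower. None of these calls held with an estimated correlation, with adjusted p = 0.881 to 0.942 with an estimated correlation for the 7 lists. For the progenitor, cytokine, LXR, glycolysis and lysosome lists, of which camera called none, the median, the mean and the test differed in sign.

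**Figure D2:**
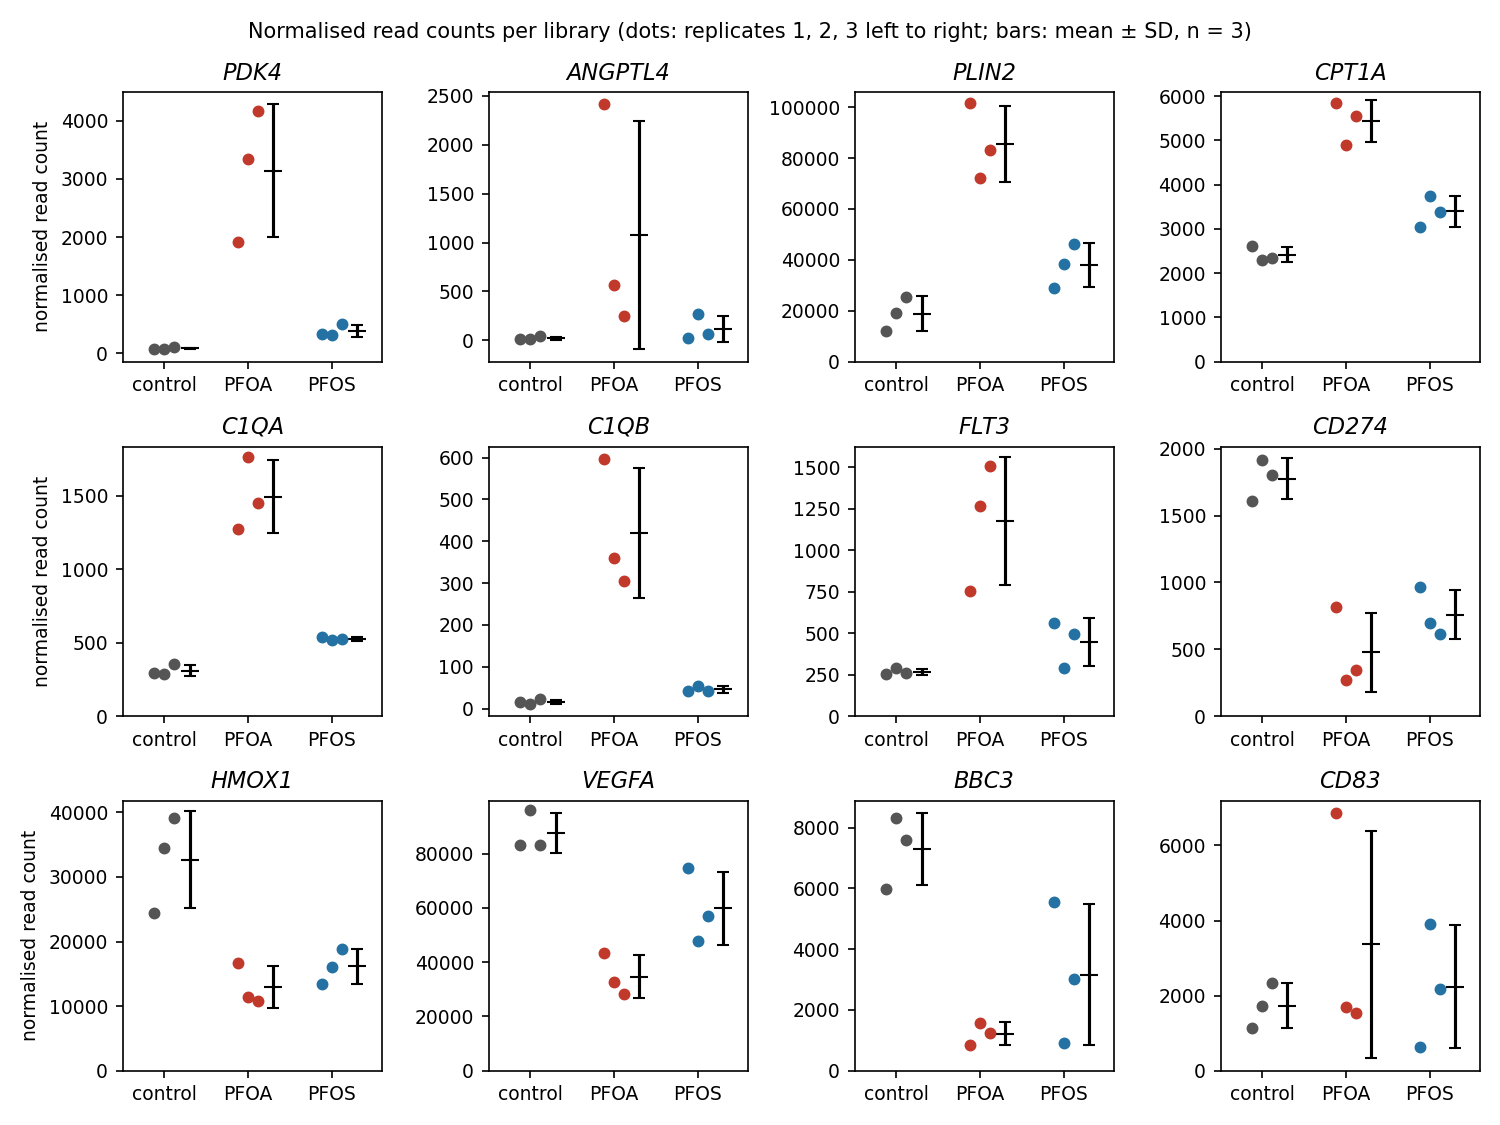
Normalised read counts of 12 genes in each library, with replicates 1 to 3 as points from left to right and the mean ± SD (n = 3) as bars. PDK4 lay between 1912 and 4170.2 with PFOA, between 318 and 500.1 with PFOS and between 70.5 and 101 in controls.

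**Figure D3:**
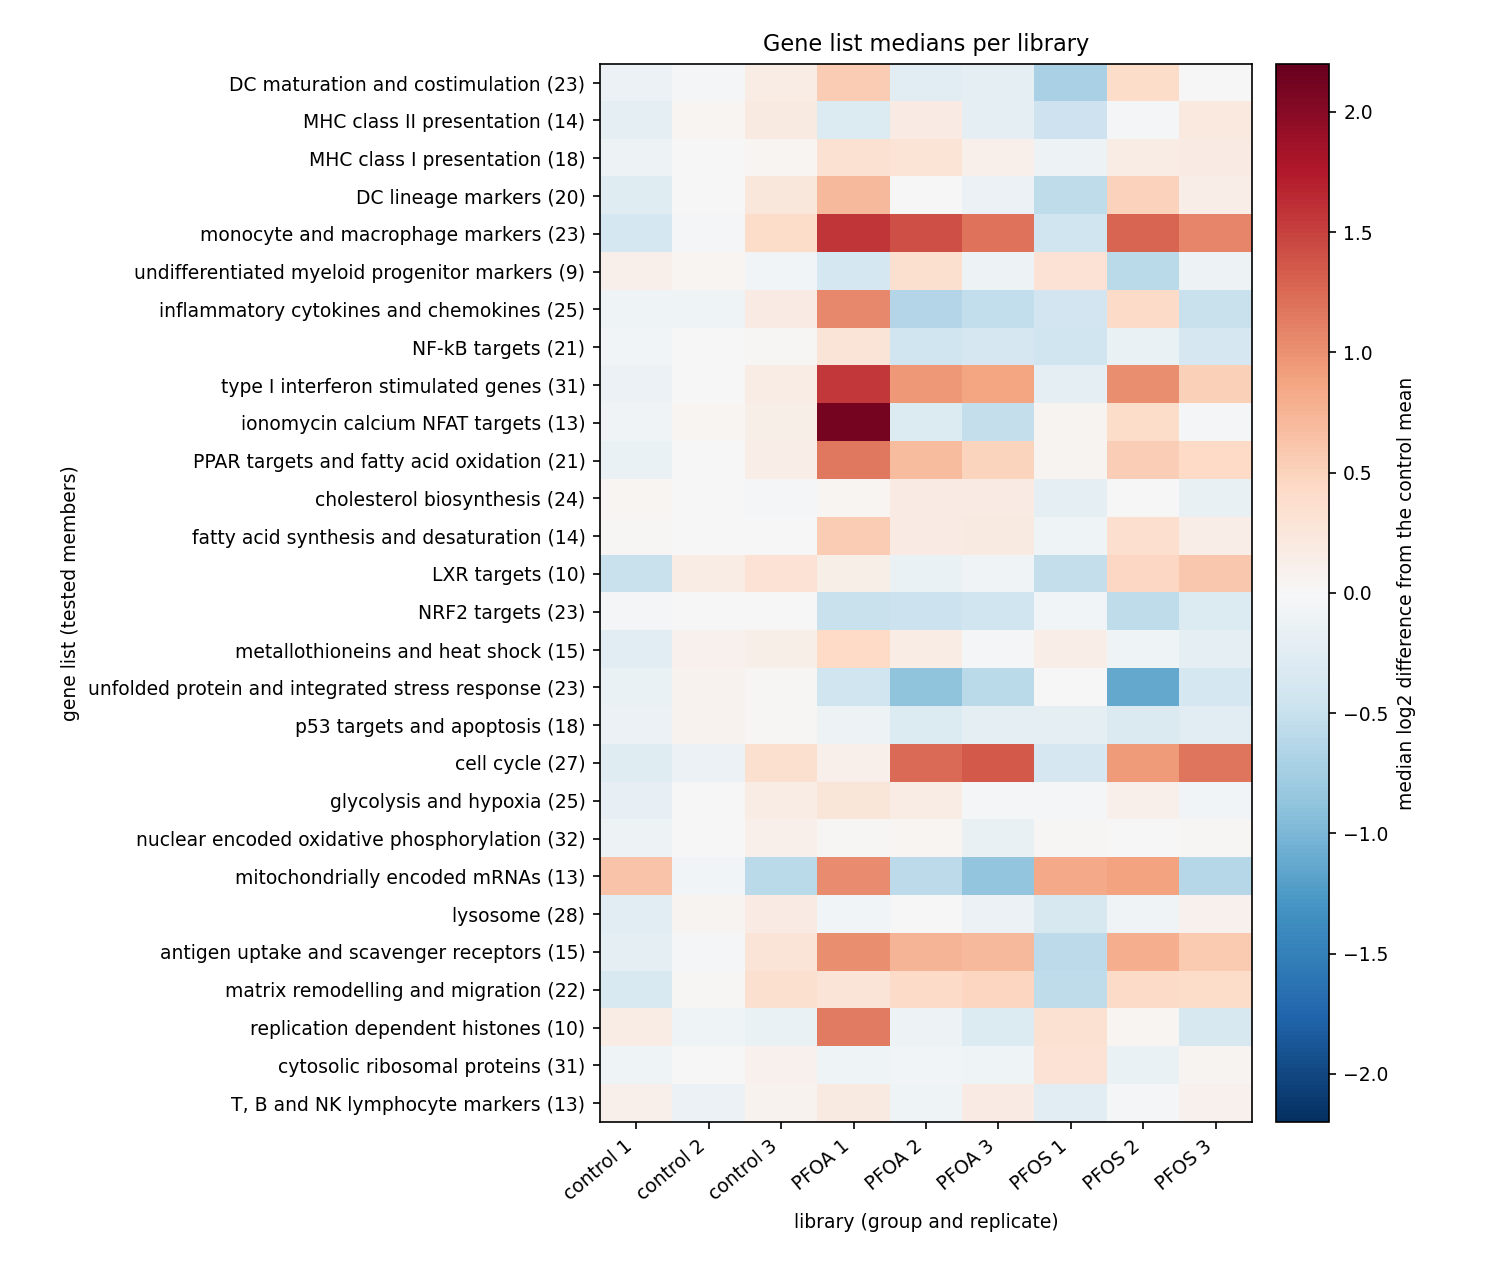
Median log2 difference from the control mean over the tested members of 28 gene lists (rows, members in brackets) in each of the 9 libraries (columns). Monocyte and macrophage markers have a median of -0.44 in PFOS replicate 1 and 1.28 in PFOS replicate 2.

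PFOS was compared with vehicle in the same way. No gene passed the test. PDK4 was 385 ± 100.4 with PFOS against 83.2 ± 15.8 in controls (log2 difference 2.18, adjusted p = 0.355), PLIN2 37883 ± 8599 against 18836 ± 6793 (1.05, adjusted p = 0.384) and CPT1A 3397 ± 353 against 2420.0 ± 162 (0.49, adjusted p = 0.384). In these 3 genes the PFOS and control libraries did not overlap, which held for 19.3% of all genes tested where chance gives 10%. PFOS and control libraries overlapped in CD80 (242 ± 102 with PFOS), CD83 (2240.0 ± 1634) and CD86 (4592 ± 2874), and PFOS replicate 1 had the lowest value of the 9 libraries in each.

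limma called 0 genes with PFOS, with 2347 at an unadjusted p under 0.05, edgeR and limma-voom called 0 and DESeq2 146 (85 higher and 61 lower). Without PFOS replicate 1, limma called 1815 genes, 843 higher and 972 lower, and with any other library left out it called 0. Sample weights gave 7198 calls, and leaving out PFOA replicate 1 and PFOS replicate 1 together, after seeing the data, gave 4486. Adjusted over the list alone, 4 PPAR targets and 3 monocyte and macrophage markers were higher, and 5 NRF2 targets, 3 aryl hydrocarbon receptor targets, 1 NF-kB target and 1 lysosome gene lower. camera placed PPAR targets (5.5e-06), cell cycle genes (7.82e-05), monocyte and macrophage markers (0.00208) and interferon-stimulated genes (0.0224) higher with PFOS, and stress, NF-kB, NRF2, lysosome and p53 genes lower (adjusted p = 0.00154 to 0.0343). None of these 9 calls held, with adjusted p = 0.881 to 0.942 with an estimated correlation. The lists called higher were not raised alike in PFOS replicates 1, 2 and 3. Their medians were 0.05, 0.54 and 0.43 for PPAR targets and -0.38, 0.93 and 1.18 for cell cycle genes. They were -0.44, 1.28 and 1.08 for monocyte and macrophage markers and -0.21, 1.03 and 0.52 for interferon-stimulated genes. Median, mean and test differed in sign for the maturation, progenitor and heat shock lists, which were not called.

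The compounds were compared directly at 10 µg/mL. PDK4, C1QB and C1QA were lower with PFOS than with PFOA, and no gene was called higher. C1QB was 46.2 ± 7.77 with PFOS and 421 ± 156 with PFOA (log2 difference -3.11, 95% interval -3.87 to -2.35, limma adjusted p = 0.0414). PDK4 differed by -2.98 (-3.67 to -2.30, adjusted p = 0.0414) and C1QA by -1.49 (-1.88 to -1.10, adjusted p = 0.0498). Other lipid genes did not pass, with differences of -1.19 for PLIN2 (95% interval -1.81 to -0.56), -0.68 for CPT1A (-0.98 to -0.38) and -3.19 for ANGPTL4 (-5.38 to -0.99). For maturation markers the intervals were wide, at -1.42 to 0.55 for CD80, -2.14 to 0.99 for CD83 and -1.79 to 0.50 for CD86, so these data do not show that the compounds act alike on them.

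The 3 calls stood beside 514 genes at an unadjusted p under 0.05 (2.62%, where chance gives 5%), and PFOS and PFOA libraries were fully separated in 4.96% of genes, where chance gives 10%. Without any 1 of the 3 controls, PFOA replicate 2 or 3, or PFOS replicate 2 or 3, 0 genes were called; without PFOA replicate 1 only PDK4 was, and without PFOS replicate 1 only 1 gene, not among these 3. Over the 9 fits with a library left out, adjusted p ran from 0.0532 to 0.362 for C1QB, 0.0115 to 0.362 for PDK4 and 0.0849 to 0.38 for C1QA. The count was 5 with quantile scaling, 5 with no filter, 0 with controls left out of the fit, 14 with sample weights and 27 by DESeq2. It was 2 with TMM scaling, robust variances or edgeR, where C1QA lost its call (adjusted p = 0.0698 by edgeR). Of 22 alternatives, 9 called C1QA, 11 C1QB and 14 PDK4. Adjusted over the list alone, 5 PPAR targets, 4 monocyte and macrophage markers and 1 gene each of the dendritic cell lineage, cytokine and lymphocyte lists were lower with PFOS. camera called 12 lists, with PPAR targets (9.44e-12), interferon-stimulated genes (2.51e-11), monocyte and macrophage markers (8.44e-09), cholesterol synthesis (5.5e-06), uptake receptors, MHC class I, cell cycle, matrix and heat shock genes lower with PFOS than with PFOA, and ribosomal protein, NRF2 and mitochondrially encoded genes higher. Without PFOS replicate 1 the cell cycle list was instead called higher with PFOS (adjusted p = 0.0175), and the matrix list was higher without a call (adjusted p = 0.724). None of the 12 calls held, with adjusted p = 0.663 to 0.942 with an estimated correlation. For the class II, progenitor, NF-kB, LXR and glycolysis lists, which were not called, median, mean and test differed in sign.

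Fold changes with PFOA and with PFOS were also compared across genes. Over 19593 genes, which are not independent replicates, the log2 fold changes with PFOA and PFOS had Pearson's r = 0.892 and Spearman's rho = 0.879. Unchanged groups simulated against the same controls gave a mean r of 0.531 (range -0.740 to 0.975 over 100 draws) and a mean rho of 0.503 (range -0.731 to 0.969). The covariance was 0.375 against a simulated mean of 0.0973 (range -0.0971 to 0.472), a difference of 0.278. The signs matched in 86.8% of genes, against 69.8% simulated (range 20.4 to 94.0%). All these observed values lay inside the simulated range. That range cannot decide whether the compounds share a response. It gave every library 1 pooled spread, although the median SD was 0.17 in controls, 0.28 with PFOA and 0.37 with PFOS. The shared control noise may thus be too large in it. Its residuals also hold the gap between PFOS replicate 1 and PFOS replicates 2 and 3. With 0 calls for PFOS the lists of called genes shared 0 genes. Without PFOS replicate 1, the PFOS library least like PFOA, they shared 819 higher genes, where independent lists of those sizes share 106, and 941 lower genes, where they share 128. With every library kept, DESeq2 called 85 genes higher with PFOS, over 15024 genes with a value in both comparisons. All 85 were also called higher with PFOA, where independent lists share 10.9. Of 61 lower genes 59 were shared, where independent lists share 7.79. The 3 controls cannot be split into parts of 2, and part of either excess, or all of it, may come from the shared controls. In the limma lists, leaving out PFOS replicate 1 may add to it.

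**Figure D4:**
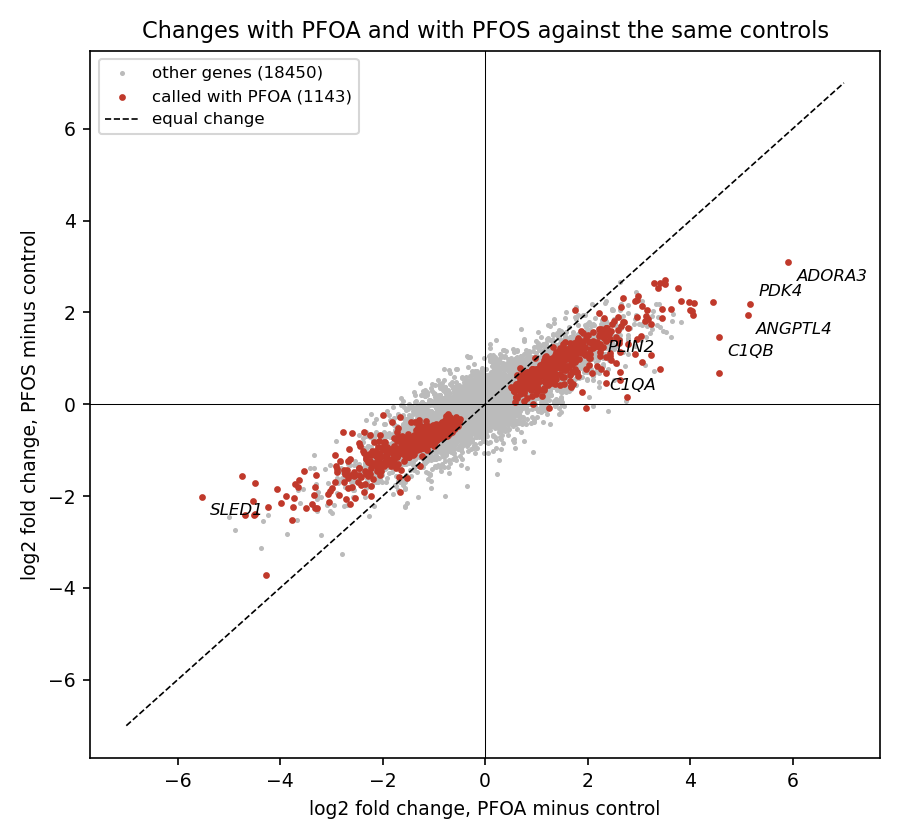
log2 fold change with PFOS against that with PFOA for 19593 genes, both relative to the same 3 controls, with the 1143 genes called with PFOA in red and the line of equal change dashed. PDK4 lies at 5.17 with PFOA and 2.18 with PFOS.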

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

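Other splits of the samples were planned before the results were seen, and the tests of a library left out, swapped, wrongly labelled or shallow and of a smaller common response were chosen after.

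C1QB (log2 difference -3.11), PDK4 (-2.98) and C1QA (-1.49) stand out because the direct test found them lower with PFOS than with PFOA. PFOS replicate 1 alone does not account for them, since their median difference was -2.90 without it, against -2.98. Whether PFOS gave a smaller response in all genes alike stays open: these genes showed 0.319, 0.422 and 0.338 of their PFOA change with PFOS, inside the middle 90% (0.280 to 0.837, median 0.626) of the 464 genes called higher with PFOA, and they were picked for a low PFOS change. The lower molar dose of PFOS was not tested. The comparison gave 3 genes in the real split and at most 0 in the others; 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

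The 8 PPAR targets called with PFOA, PDK4 among them, showed a median share of 0.446 with PFOS, against 0.626 for all 464 genes called higher. Without PFOS replicate 1 these medians were 0.545 and 0.794. The list was looked at because it was lower with PFOS and its members are correlated, so these values do not decide whether PPAR targets responded less than other genes.

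PFOS replicate 1 lies with the controls. A swap with a control is argued against, since over all 19593 genes no control lay more than 0.202 of the way from the other controls to PFOA, where PFOS replicates 1, 2 and 3 lay at 0.0578, 1.08 and 0.598. Depth is argued against, since it had 76241530 reads (76.2 in units of 1e+06), more than PFOS replicate 3 with 74930790. An unexposed library with a PFOS label stays open. Over the called genes, which all 3 controls helped to choose, PFOS replicate 1 lay at 0.242 and the highest control at 0.0776. Earlier rules for this question were each changed after their values were seen. They used the PPAR list median, the called genes, or all genes with 3 raised genes. The PPAR list median of PFOS replicate 1 was 0.05, with the highest control at 0.23. By the other rules the question could not be decided. A further test, made after all those values were seen, used 1143 genes chosen without PFOS and without the control compared. With control replicate 1, 2 or 3 left out, PFOS replicate 1 lay at 0.142, 0.0252 and 0.0566 (mean 0.0747). The control left out lay at 0.114, -0.109 and 0.187. These positions measure movement towards PFOA only. They cannot tell an unexposed library from an exposed one that changed in other genes. A response that was weak over most genes stays open too. PDK4 at 335 and C1QA at 537 lay above all 3 controls although picked for a low PFOS value, and HMOX1 at 13483 lay below them. In PDK4, C1QA and C1QB the change of PFOS replicate 1 was not weak among PFOS libraries. Their median log2 difference from controls was 1.31, 1.72 and 1.34 in PFOS replicates 1, 2 and 3. Controls, each against the other controls, lay between -0.18 and 0.44. As picked genes in 1 library, these do not settle its exposure.

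PFOA called 1143 genes in the real split and at most 0 in the others, with 1 of the 10 splits reaching the real count; PFOS called 0 in all 10 splits. Again 10 splits are too few for a share under 0.05. In each comparison, PFOS against PFOA included, every other split also mixes both groups. This puts any group difference into the spread and lowers gene calls, so 0 calls there give the real split no support. For gene lists, as many camera calls came from 9 of 10 splits for PFOA (7 calls in the real split, 15 in the highest other), 7 of 10 for PFOS (9 and 16) and 4 of 10 for PFOS against PFOA (12 and 14). Splits that mix the groups keep part of the group difference, and the preset correlation of 0.01 lies below estimated correlations of up to 0.970; which of these raised the counts was not tested.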

How the results depend on the processing

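The limma-voom fit and the fit without PFOA replicate 1 and PFOS replicate 1 were chosen after seeing the data. All 68 genes called with PFOA that the naming rule picked kept their direction under every alternative that gave them a value, and PDK4, C1QA and C1QB stayed called whichever library was left out (highest adjusted p 0.00798, 0.02 and 0.0142). Of 6133 pairs of a named gene and an alternative, 584 lost and 122 gained a call, and 271 changed sign with no call on either side. PFOA calls ranged from 3 to 5051 with 1 library left out, against 1143. They numbered 433 with no filter, 5352 with the 2 groups alone, 8688 with sample weights, 4283 by DESeq2 and 4619 without both libraries. PFOS calls ranged from 0 to 1815 with 1 library left out and were 7198, 146 and 4486 in the last 3 of these settings. PFOS and PFOA differed in 0 to 1 genes with 1 library left out, 5 with quantile scaling, 5 with no filter, 0 with the 2 groups alone, 14 with weights and 27 by DESeq2. PFOS libraries enter the PFOA comparison only through the shared estimate of the spread and its degrees of freedom. The 5051, 4165 and 16 PFOA calls without PFOS replicate 1, 2 or 3 thus differ from 1143 through these alone. The cause of the other differences was not tested. The correlation of fold changes was 0.768 with no filter and ranged from 0.659 to 0.920 with 1 library left out. The 28 list calls became 0 with an estimated correlation. By fry, which asks whether a list changed by itself, there was 1 call, PPAR targets higher with PFOA (fry adjusted p = 0.0493). Of the PFOS minus PFOA lists, cytokines were called higher without PFOA replicate 1, and class II and cell cycle genes without PFOS replicate 1. Without a call, matrix genes turned higher without PFOS replicate 1, cytokines without PFOS replicate 1 (adjusted p = 0.549) or 3 (0.829), and class II genes without PFOA replicate 2 (0.363) and at a mean of at least 50 (0.912). In the order cytokines, class II, cell cycle and matrix, adjusted p ranged over left-out libraries from 7.29e-05 to 0.934, 0.0376 to 0.976, 6.6e-10 to 0.733 and 0.00014 to 0.724. Over all genes the replicate numbers showed no common pairing. Deviations of same-numbered libraries correlated at -0.0879, 0.0282 and -0.0757 between control and PFOA, 0.213, -0.219 and 0.363 between control and PFOS, and -0.317, -0.248 and 0.200 between PFOA and PFOS. Cell cycle medians, however, rose with the replicate number in every group (-0.26, -0.13 and 0.36 in controls, 0.11, 1.24 and 1.35 with PFOA, -0.38, 0.93 and 1.18 with PFOS). Calcium genes showed no common order (-0.08, 0.05 and 0.12 in controls, 2.11, -0.31 and -0.53 with PFOA, 0.06, 0.40 and -0.04 with PFOS). Mitochondrially encoded mRNAs were lowest in replicate 3 of every group (-0.59 in controls, -0.86 with PFOA and -0.64 with PFOS). A replicate effect on some genes therefore stays open. With the replicate number as a block, 17 genes were called with PFOA, 0 with PFOS and 1 between the compounds. Cytokines then turned higher with PFOS than with PFOA without a camera call (adjusted p = 0.877).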

Other observations

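These values were picked after the data were seen, and no test was made of them. Some genes differed widely between libraries of a group. FOS was 10464, 4838 and 3629 in PFOA replicates 1 to 3 and 549, 6440.3 and 1968 in PFOS replicates 1 to 3, and EGR1 was 10237, 3585 and 2641 and 847, 5730.4 and 2261. CD83, a maturation marker, was 6859 in PFOA replicate 1 and 3909.8 in PFOS replicate 2, against 1700.2 and 1538 in the other PFOA libraries.

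Mitochondrially encoded mRNAs varied inside every group and were lowest in replicate 3 of each. Their median log2 difference from the control mean was 0.63, -0.05 and -0.59 in the controls, 1.04, -0.58 and -0.86 with PFOA and 0.83, 0.88 and -0.64 with PFOS.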
